A study of Sus scrofa with 22 samples.

How the data were processed

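The deposited table held signal intensity per probe set of an Affymetrix porcine array for 22 samples, made with GCOS 1.1.1 per the submitters' processing notes. Per the labels, total RNA was isolated with TRI Reagent, treated with DNase, cleaned on RNeasy columns and made into biotinylated cRNA from 0.5 µg. The deposited intensity values were linear, from 1 to 111760, and the mean after trimming 2% at each end was 500 on every array, so the arrays had been scaled to a common trimmed mean. The planned scale for linear values, log2(signal + 16), was therefore used without further normalization. Fold changes are taken on this scale and understate the change of dim genes. Of 24123 probe sets 124 controls were left out and 23999 were tested. Of these, 10069 carried 1 gene symbol (6765 different symbols), 198 carried several and were not named, and 13732 had no name in the annotation used here. Symbols were updated through the gene identifier in the RefSeq table, which held the identifier of 9961 of the named probe sets and lacked that of 108. A list member absent under its symbol was matched under an older name only when that symbol was not itself current, because MKI67 is also recorded as an older name of another gene. No genome coordinates were used.

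Stages were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 mean per stage, moderated variances, an F test over the 4 stages and 4 comparisons, and Benjamini-Hochberg adjustment over the 23999 probe sets of each test. A probe set was called at an adjusted p under 0.05. Probe sets highest or lowest at 1 dpn were those called in opposite directions in the 2 steps around it. The p-values treat animals as independent, although offspring of 3 gilts were collected per stage and the gilt of each animal is not given in the sources used here. The number of arrays, 6, 6, 6 and 4, limits precision. All animals came from dams on the same diet, so no effect of diet could be tested. Spread was the median SD over probe sets. The table carries no detection calls, so background was set at the 95th percentile of 23 control probe sets whose targets were absent, a signal of 69.7 (log2 6.42 on the scale used). Where all values of a gene at the dimmer stage lay below background, the fold is given as a lower bound against background. Where only the mean of the dimmer stage lay below background, the 2 mean signals are given instead of a fold.

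Named genes followed a rule fixed before the files were opened. The rule took, per comparison, the 8 largest called rises and 8 largest called falls without overlap between animals, with 1 probe set per gene chosen by the change in that comparison. Levels of a gene can therefore come from different probe sets in different comparisons. It also took up to 4 called members of each list, by the probe set with the highest mean, and 13 genes chosen in advance, of which H19 and MKI67 had no annotated probe set. The 36 fixed lists were tested with camera on the brightest probe set of each gene, with its preset correlation of 0.01, adjustment over lists and comparisons, and at least 5 measured genes. A second run estimated the correlation within each list from the data. The fixed lists covered fetal and imprinted growth, erythroid cells, cell cycle, liver metabolism and secreted proteins, hormone axes, mitochondria, ribosomes, peroxisomes, iron, chromatin, interferon response, immune cells, matrix, cholangiocytes, endothelium, muscle, adipocytes, pancreas, stress and clock genes. A further 11 lists of muscle and nerve genes were written after the muscle signals were seen and adjusted apart. They covered fast-twitch, slow-twitch and embryonic muscle genes, myogenic regulators, glycolysis, the tricarboxylic acid cycle, calcium handling, the Z-disc, the neuromuscular junction, proteasome and atrophy genes, and Schwann cells.

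Results were also computed with quantile normalization, each array centred on its median, a pseudocount of 1, trended and robust variances, array weights, fits on only the stages compared, probe sets brighter than the median one, the mean of the probe sets of a gene, an estimated correlation and each sample left out. Further settings were chosen after the data were seen. They were only the 1 dpn arrays with even or with low 5' signal, the GAPDH 5'/3' ratio as a covariate, leaving out the 2 arrays with most liver or pancreas transcripts, the added lists, centring for lists, and the pseudocount of 1 for lists and named genes. In a self-test on data with known changes in 66 or 67 probe sets each, a change of log2 2 was called in 81.8, 86.4, 75.8 and 80.3% over the 4 comparisons, log2 1 in 26.9, 28.4, 28.4 and 29.9%, and log2 0.5 in 1.49, 4.48, 2.99 and 4.48%. False calls were 2, 7, 2 and 6 of 23999 probe sets. With no list shifted 0 list tests were called, and a shift of log2 0.5 in the 58 oxidative phosphorylation genes gave an adjusted p of 8.8e-52. The simulated probe sets varied independently of one another. The self-test therefore cannot show how often lists of correlated genes, or animals that share a litter or batch, give false calls. In this self-test a change of log2 1 was missed in most probe sets. Far fewer probe sets were changed there than were called in the data, which makes the adjusted threshold stricter. The percentages therefore do not carry over to the real comparisons. Absence of a call is still weak evidence of no change. Artifact tests split the animals into groups of the same sizes 100 times.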

Results

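Transcript levels were compared between 4 ages of pigs whose dams had eaten an adequate protein diet in gestation. The ages were 94 days after conception (94 dpc, 6 animals) and 1, 28 and 188 days after birth (1 dpn, 6 animals; 28 dpn, 6 animals; 188 dpn, 4 animals). Every sample label named liver, whereas the series title named muscle. The brightest named gene over the 22 arrays was the myosin light chain MYL1 (mean signal 68608), followed by the tropomyosin TPM1 (62952), GAPDH (61720), the myosin light chain MYLPF (61530) and the muscle creatine kinase CKM (61521). Of the 30 brightest named genes, 11 belonged to a skeletal muscle list fixed before the data were examined and 0 to the liver gene lists. The tissue is called muscle-like here after these bright signals, although brightness also depends on the probe set.

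Between any of the 4 stages, 12333 of 23999 probe sets differed (51.4%, limma F test, adjusted p under 0.05), and these covered 4632 named genes. Of the 3 steps between successive ages the largest was that from 94 dpc to 1 dpn, with 7836 probe sets changed (2626 higher, 5210 lower; 3131 named genes). This step spans late gestation and birth, and no sample separates them. From 1 dpn to 28 dpn 5357 changed (3344 higher, 2013 lower; 2389 genes), against 3347 (2140 higher, 1207 lower) when only these 2 stages were fitted. From 28 dpn to 188 dpn 2843 changed (876 higher, 1967 lower; 1191 genes), and without replicate 2 of 188 dpn 552 were higher and 1376 lower. Over the whole span from 94 dpc to 188 dpn 8683 changed (3274 higher, 5409 lower; 3350 genes), and 6001 of these differed at least by log2 1. In the same order, the counts of at least log2 1 for the 3 steps were 4359, 2722 and 1620. The split into higher and lower depended on the scaling of the arrays. The percentages called higher were 33.5, 62.4, 30.8 and 37.7 as deposited, 47.4, 49.8, 44.2 and 48.6 after quantile normalization, and 57.7, 39.7, 60.1 and 56.2 with each array centred on its median. The median probe set shifted by log2 -0.08, 0.10, -0.12 and -0.07 as deposited. Offspring of 3 gilts were collected per stage and no label ties an animal to a gilt, so all p-values over animals are too small if littermates resemble one another.

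**Figure D1:**
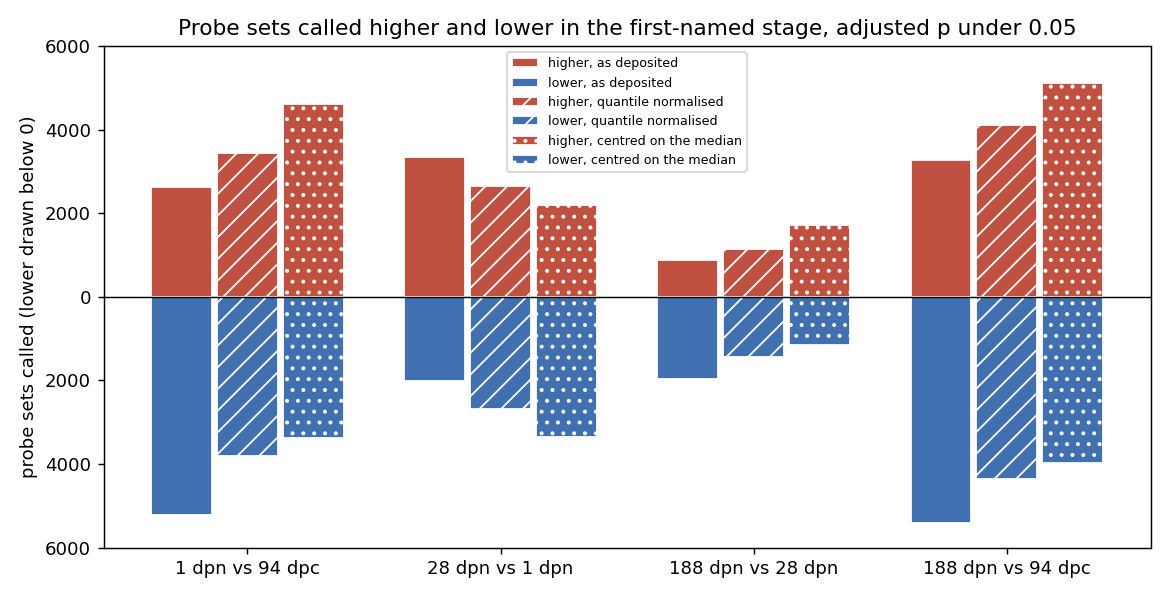
Probe sets called higher (up) and lower (down) in each comparison of stages, with values as deposited, after quantile normalization and with each array centred on its median. From 94 dpc to 1 dpn, 2626 were higher and 5210 lower as deposited, against 4618 and 3385 with centring.

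From 94 dpc to 1 dpn lists of energy metabolism were called up in the muscle-like tissue, and lists of embryonic muscle, cell cycle and matrix genes were called down, although 0 of these calls held with an estimated correlation. The mitochondrial creatine kinase CKMT2 rose from a mean signal of 1376 (SD 266) to 40585 (SD 12036), 28.3-fold (log2 4.82, SE 0.21, n = 6 and 6, adjusted p = 1.2e-12). PDK4, which restrains the entry of pyruvate into mitochondrial oxidation, rose 27.0-fold (300 to 10372, log2 4.76, SE 0.48, adjusted p = 2.1e-07). The embryonic myosin light chain MYL4 fell 30.8-fold (6813 to 215, log2 -4.95, SE 0.26, adjusted p = 3.8e-11), and the growth factor MDK fell 36.7-fold (log2 -5.20, SE 0.39, adjusted p = 6.2e-09). On only the 2 arrays of 1 dpn with even 5' signal, described further below, the log2 changes of these 4 genes were 4.20, 5.11, -4.90 and -4.59. Other large rises were those of the ATP synthase subunit ATP5I (27.4-fold), the autophagy gene TP53INP2 (22.8-fold), the small heat-shock protein HSPB7 (12.7-fold), angiotensinogen AGT (11.5-fold), FKBP5 (11.1-fold) and the myosin MYO5B (11.0-fold). Other large falls were those of the troponin TNNT2 (33.1-fold), the matrix gene POSTN (18.6-fold), C3H2orf40 (13.1-fold) and the imprinted noncoding RNA MEG3 (12.7-fold). The copper transporter SLC31A2 (563 to 23.4) and, by 1 probe set, IGSF1 (806 to 49.3) fell to means below background. By another IGSF1 probe set the median at 1 dpn was 856, above background, so its level there depends on the probe set. On the even arrays alone the fall of MEG3 was log2 -1.56, against -3.67 with all arrays and -4.28 without replicate 1 of 1 dpn, and the changes of ATP5I and TNNT2 were 3.48 and -4.09, against 4.78 and -5.05.

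Mitochondrial lists were called up from 94 dpc to 1 dpn. Of 58 measured oxidative phosphorylation genes, 52 were higher and 0 lower (53 and 1 when adjusted over the list alone), with a list test adjusted p = 4.4e-24 that became adjusted p = 0.157 with an estimated correlation. Examples were the electron carrier CYCS (log2 2.66), the complex I subunit NDUFC1 (2.65, and 1.49 on the even arrays) and the complex III subunit UQCRB (2.33). Fatty acid oxidation and ketogenesis had 21 of 30 genes higher and 0 lower (22 and 0 over the list alone; adjusted p = 8.9e-10, and adjusted p = 0.157 with an estimated correlation), among them the acyl-CoA synthetase ACSL1 (log2 2.60) and the very-long-chain dehydrogenase ACADVL (2.52). All 21 measured genes of the tricarboxylic acid cycle were higher (adjusted p = 1.2e-14, and adjusted p = 0.0869 with an estimated correlation), with MDH1 at log2 2.61 and IDH3A at 1.96. This cycle list is one of 11 lists written after the muscle signals had been seen. Glycolysis, also added then, had 11 of 18 genes higher and 1 lower (adjusted p = 9.5e-05, and adjusted p = 0.254 with an estimated correlation), and on the even arrays its adjusted p was 0.0987. Phosphofructokinase PFKM was 2.70-fold higher with all arrays (log2 1.43) and not called on the even arrays (log2 0.68, adjusted p = 0.0823).

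Contractile genes moved in 2 directions from 94 dpc to 1 dpn. Of 27 genes in the skeletal muscle list 13 were higher and 2 lower (16 and 2 over the list alone; adjusted p = 0.00091, and adjusted p = 0.355 with an estimated correlation), but after quantile normalization the direction was down with an adjusted p of 0.723. The fast calcium pump ATP2A1 rose 9.83-fold (1994 to 19175, log2 3.30, SE 0.21), glycogen phosphorylase PYGM 3.81-fold and the slow myosin light chain MYL3 3.27-fold. On the even arrays the change of PYGM was log2 0.97, against 1.93 with all arrays. MYBPC1 fell 2.48-fold, a change not called on the even arrays (log2 -0.67, adjusted p = 0.199). The added list of embryonic and neonatal muscle genes had 5 of 7 lower and 1 higher (adjusted p = 0.0096, and adjusted p = 0.151 with an estimated correlation). The median over its 7 genes averaged log2 12.71 over the arrays of 94 dpc and 7.82 over those of 1 dpn. That median is the level of the middle gene and not the fall of each member, of which NCAM1 changed by log2 -1.61. Fast-twitch genes, an added list, had 6 of 10 higher and 0 lower (7 and 0 over the list alone; adjusted p = 0.0020, and adjusted p = 0.273 with an estimated correlation), with an adjusted p of 0.853 after quantile normalization and 0.0874 on the even arrays. The added list of the Z-disc had 13 of 20 higher and 3 lower (14 and 3 over the list alone; adjusted p = 0.0011, and adjusted p = 0.231 with an estimated correlation), but 0.376 after quantile normalization. Its stress-responsive member ANKRD1 rose 6.92-fold (log2 2.79, SE 0.60, and 4.34 on the even arrays) and the chaperone CRYAB 3.27-fold.

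Cell cycle, chromatin, matrix and endothelial lists were called down in the same step. Of 31 cell cycle genes 26 were lower and 0 higher (28 and 1 over the list alone; adjusted p = 8.9e-10, and adjusted p = 0.142 with an estimated correlation). The ubiquitin-conjugating enzyme UBE2C fell 9.91-fold, CKS2 7.41-fold and the cyclin CCNB1 5.57-fold, and the kinase AURKB fell from 452 to 55.4. On the even arrays the change of UBE2C was log2 -4.44, against -3.31 with all arrays. Chromatin regulators had 9 of 17 lower and 0 higher (9 and 1 over the list alone; adjusted p = 0.0265, and adjusted p = 0.374 with an estimated correlation), with EZH2 at log2 -1.76 and HMGB2 at -1.57, and on the even arrays the list had an adjusted p of 0.0627. Matrix genes had 20 of 31 lower and 2 higher (20 and 3 over the list alone; adjusted p = 0.00051, and adjusted p = 0.408 with an estimated correlation), including ASPN (8.15-fold lower; log2 -3.03, -4.65 on the even arrays, and -2.38 without replicate 1 of 1 dpn) and the collagen COL1A2 (4.50-fold lower). Endothelial genes had 13 of 21 lower and 0 higher (14 and 0 over the list alone; adjusted p = 0.00013, and adjusted p = 0.141 with an estimated correlation), including RAMP2 (log2 -2.45), CLDN5 (-2.01), TIE1 (312 to 52.6) and ANGPT2 (267 to 47.6).

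From 94 dpc to 1 dpn glucocorticoid-responsive genes had 9 of 21 higher and 2 lower (10 and 2 over the list alone; adjusted p = 0.0146, and adjusted p = 0.256 with an estimated correlation), but 0.0777 after quantile normalization and 0.0532 with centring. FKBP5 rose from 89.3 to 1235 and KLF9 by log2 2.41, while the glucocorticoid receptor NR3C1 had a change of log2 -2.96 (-1.77 on the even arrays). The list of the growth hormone and insulin-like growth factor axis was not called (5 of 16 lower, 0 higher, adjusted p = 0.163), but its member IGF1 fell to a mean below background (250 to 43.8, adjusted p = 1.2e-06). IGF2 fell 2.53-fold by its brightest probe set (10399 to 4160, log2 -1.34, SE 0.36, adjusted p = 0.0062), and on the even arrays the fall was not called (log2 -1.15, adjusted p = 0.140). Of the other IGF2 probe sets 5 were also called lower (log2 -1.22 to -2.40), and 2 dimmer ones went the other way. These were at log2 0.72, with means below background at both stages (11.5 and 29.6), and at 1.15. Ribosomal protein genes had 26 of 59 higher and 2 lower (28 and 4 over the list alone; adjusted p = 0.00032, and adjusted p = 0.566 with an estimated correlation), with RPL27 at log2 0.87 and RPL31 at 0.81, but the direction reversed to down after quantile normalization (adjusted p = 0.0016). Proteasome and atrophy genes, an added list, had 19 of 34 higher and 1 lower (adjusted p = 4.4e-07, and adjusted p = 0.231 with an estimated correlation), with the proteasome subunit PSMD14 2.82-fold higher.

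**Figure D2:**
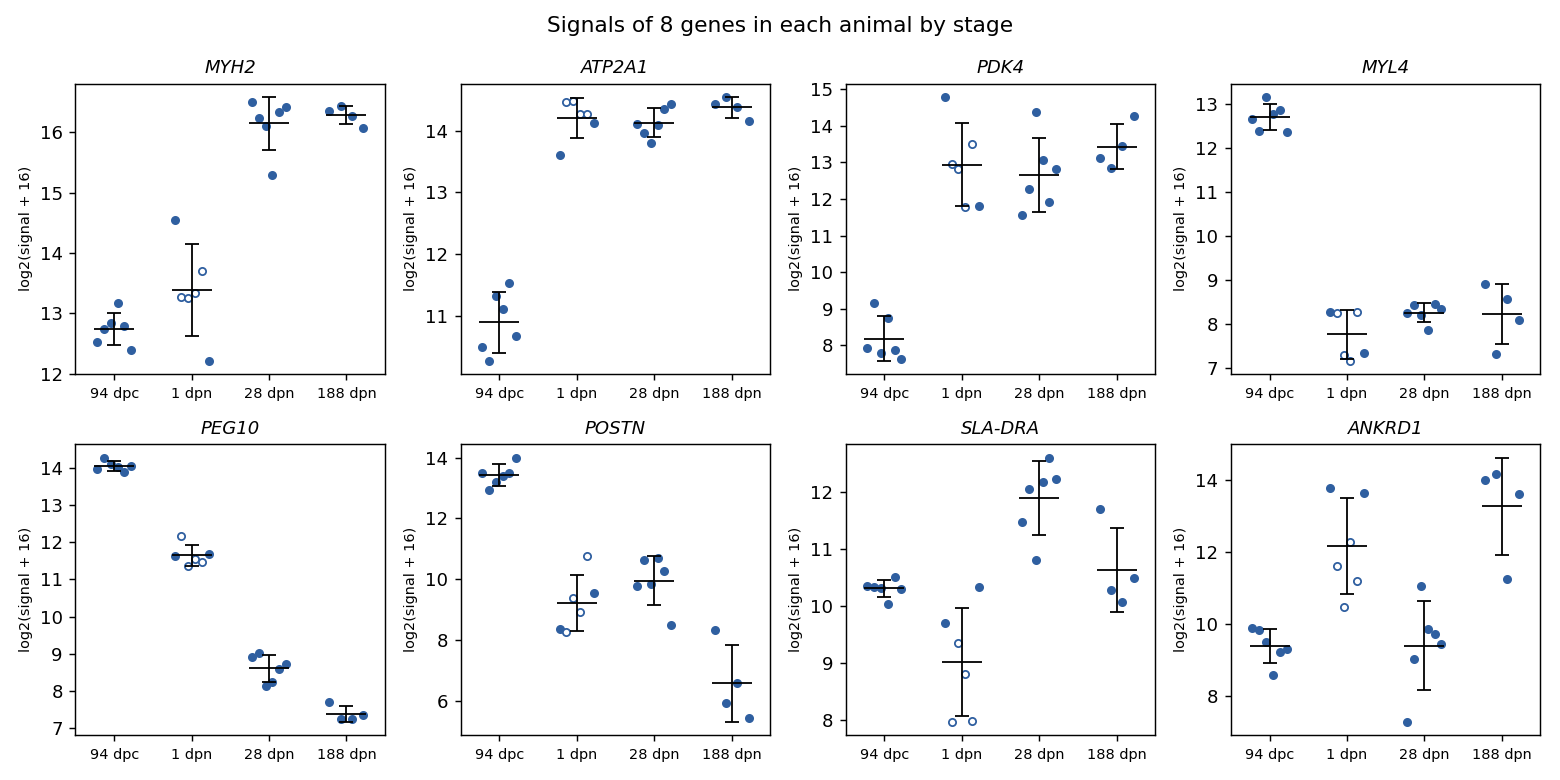
Signal of 8 genes as log2(signal + 16) in each animal by stage, with bars for mean and SD; open points are the 4 arrays of 1 dpn with low 5' signal. From 94 dpc to 1 dpn MYL4 fell (6813 to 215) and ATP2A1 rose (1994 to 19175), and MYH2 rose by 28 dpn (12005 to 74914).

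From 1 dpn to 28 dpn lists of fast-twitch, glycolysis and antigen-presentation genes were called up, but 0 of them with an estimated correlation. The fast myosin heavy chain MYH2 rose 6.75-fold (12005, SD 6499, to 74914, SD 18681; log2 2.76, SE 0.28, n = 6 and 6, adjusted p = 4.7e-07). Glycogen phosphorylase PYGM rose 18.1-fold by 1 probe set (574 to 10526, log2 4.18, SE 0.16, adjusted p = 8.1e-14), and GAMT, which makes creatine, rose 16.4-fold (280 to 4806, log2 4.04, SE 0.23). The imprinted gene PEG10 fell 8.27-fold (3243 to 381, log2 -3.05, SE 0.17, adjusted p = 1.0e-10). On the even arrays the log2 changes of these 4 genes were 2.76, 4.54, 4.33 and -3.06. Further rises were those of STRADB (12.7-fold), the muscle mitochondrial gene MSS51 (12.4-fold), PLBD1 (11.1-fold) and the glycerol phosphate dehydrogenase GPD1 (11.0-fold). The syntrophin SNTB1 (68.9 to 911) and PRKRA (37.2 to 433) rose from means below background. Further falls were those of MYO5B (8.80-fold), the phosphatase CDKN3 (7.94-fold), the complex I subunit NDUFA1 (7.14-fold), the imprinted gene PLAGL1 (5.24-fold), SLC25A33 (5.09-fold) and RER1 (245 to 41.1). KLK1 fell at least 3.20-fold, a bound taken against background because all of its values at 28 dpn lay below background. NDUFA1 was not called on the even arrays (log2 -2.31, adjusted p = 0.0576), where GPD1 and SLC25A33 were at log2 5.10 and -3.63, against 3.46 and -2.35 with all arrays. Without replicate 1 of 1 dpn GPD1 was at 2.80.

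Further lists called up by 28 dpn were those of muscle and of amino acid catabolism. Of 27 skeletal muscle genes 19 were higher and 0 lower (22 and 0 over the list alone; adjusted p = 2.9e-09, and adjusted p = 0.141 with an estimated correlation), among them MYBPC1 (log2 1.81), the carbonic anhydrase CA3 (1.72) and the muscle phosphoglycerate mutase PGAM2 (1.24). The added fast-twitch list had 6 of 10 higher and 0 lower (7 and 0 over the list alone; adjusted p = 7.5e-05, and adjusted p = 0.231 with an estimated correlation), and added glycolysis had 11 of 18 higher and 0 lower (adjusted p = 2.0e-06, and adjusted p = 0.231 with an estimated correlation). Glycolytic examples were PGM1 (log2 2.17), GPI (1.99), the phosphorylase kinase subunit PHKB (1.92) and PFKM (1.82). The added Z-disc list had 8 of 20 higher and 3 lower (adjusted p = 0.0083, and adjusted p = 0.273 with an estimated correlation), but on the even arrays its adjusted p was 0.0977. Its members MYOM2 and CAPN3 rose by log2 2.19 and 2.86, the latter not called on the even arrays (log2 0.91, adjusted p = 0.255) and at log2 3.56 without replicate 1 of 1 dpn. Amino acid catabolism had 7 of 25 higher and 0 lower (adjusted p = 0.0284, and adjusted p = 0.355 with an estimated correlation), including the branched-chain enzymes BCAT2 (7.78-fold; log2 2.96, and 1.98 on the even arrays), HIBCH (3.00-fold) and BCKDHB (2.29-fold). This list had an adjusted p of 0.0660 on the even arrays, 0.0863 without replicate 6 of 1 dpn and 0.0501 without replicate 1 of 28 dpn.

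The interferon-response, macrophage, endothelial and cell cycle lists were called up in the same interval. Interferon-response and antigen-presentation genes had 25 of 38 higher and 3 lower (27 and 3 over the list alone; adjusted p = 4.4e-07, and adjusted p = 0.281 with an estimated correlation). The class I gene SLA-2 rose 8.18-fold, the class II gene SLA-DRA 7.29-fold (607 to 4087) and the invariant chain CD74 6.68-fold, while SLA-DRB1 (log2 2.27) was not called on the even arrays (log2 1.19, adjusted p = 0.0698). On those arrays SLA-2, SLA-DRA and CD74 rose by log2 1.81, 1.87 and 2.07, against 3.03, 2.87 and 2.74 with all arrays. Macrophage genes had 8 of 19 higher and 0 lower (adjusted p = 0.0141, and adjusted p = 0.485 with an estimated correlation), with C1QC at log2 2.21, LAPTM5 at 2.15 and FCGR3A at 2.10. On the even arrays the macrophage list had an adjusted p of 0.175 and none of these 3 genes was called. Endothelial genes had 10 of 21 higher and 1 lower (11 and 1 over the list alone; adjusted p = 0.00068, and adjusted p = 0.141 with an estimated correlation), with RAMP2 at log2 1.81, TIE1 from 52.6 to 228 and ANGPT2 from 47.6 to 217. Cell cycle genes had 11 of 31 higher and 2 lower (13 and 2 over the list alone; adjusted p = 0.0091, adjusted p = 0.481 with an estimated correlation, and adjusted p = 0.0727 without replicate 1 of 1 dpn), with AURKB from 55.4 to 200 and UBE2C at log2 1.34, and TYMS rose at least 1.34-fold. The call of UBE2C was lost with single samples left out (highest adjusted p = 0.117).

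Some lists that were called up by 1 dpn were called down from 1 dpn to 28 dpn. Ribosomal protein genes had 19 of 59 lower and 3 higher (24 and 5 over the list alone; adjusted p = 0.0088, and adjusted p = 0.707 with an estimated correlation), with RPL3 2.66-fold lower, but on the even arrays the list had an adjusted p of 0.120. Oxidative phosphorylation had 16 of 58 lower and 2 higher (19 and 3 over the list alone; adjusted p = 0.0039, and adjusted p = 0.662 with an estimated correlation), with COX7A2 3.63-fold lower. On the even arrays alone this list had no direction to report (adjusted p = 0.999, nominally up). The added proteasome list had 10 of 34 lower and 2 higher (11 and 2 over the list alone; adjusted p = 0.0070, and adjusted p = 0.488 with an estimated correlation), and its adjusted p was 0.0612 after quantile normalization and 0.0907 without replicate 1 of 1 dpn. IGF1 rose from 43.8 to 234 (adjusted p = 5.9e-06). The fatty acid synthase FASN was 1.73-fold lower (log2 -0.79, SE 0.28, adjusted p = 0.0457) and was not called on the even arrays (adjusted p = 0.595). Its call was also lost with single samples left out (highest adjusted p = 0.120).

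**Figure D3:**
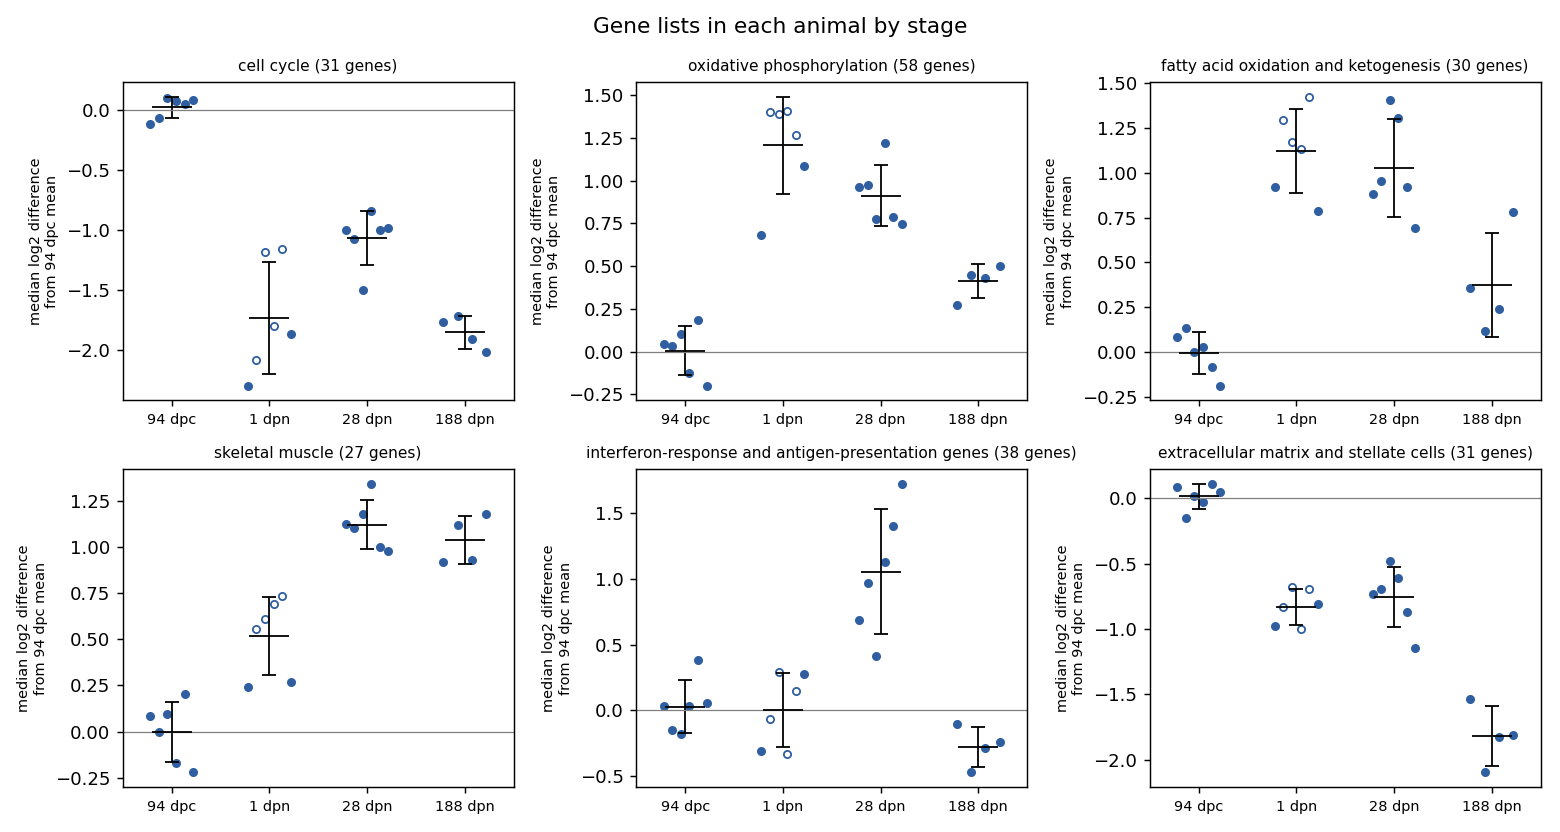
Median log2 difference from the 94 dpc mean over the genes of 6 lists in each animal by stage, with bars for mean and SD; open points are the 4 arrays of 1 dpn with low 5' signal. Interferon-response genes peaked at 28 dpn (25 of 38 higher than at 1 dpn). The list test of the skeletal muscle list from 94 dpc to 1 dpn gave no call after quantile normalization (adjusted p = 0.723).

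From 28 dpn to 188 dpn the interferon-response, matrix, slow-twitch and mitochondrial lists were called down, though 0 of them with an estimated correlation. The cardiac actin ACTC1 fell 16.3-fold (30214, SD 14327, to 3391, SD 4959; log2 -4.03, SE 0.54, n = 6 and 4, adjusted p = 6.1e-05). Beta-2-microglobulin B2M, the light chain of class I molecules, fell 9.16-fold (35278 to 3851, log2 -3.20, SE 0.30, adjusted p = 1.3e-06). ANKRD1 rose 14.7-fold (860 to 12569, log2 3.88, SE 0.67, adjusted p = 0.00070), and the germ-cell gene NANOS1 rose 8.25-fold (166 to 1425, log2 3.04, SE 0.27). ANKRD1 was at log2 4.55 without replicate 3 of 188 dpn, and ACTC1 at -4.94 without replicate 1. Other rises were those of the ubiquitin hydrolase UCHL1 (12.3-fold), TMEM140 (7.50-fold), MSS51 (6.42-fold), the malic enzyme ME1 (6.42-fold) and the heat-shock gene HSP70.2 (5.80-fold). GPX3 rose 5.54-fold (adjusted p = 0.0303), but without replicate 4 of 188 dpn its change was log2 1.62 (adjusted p = 0.151). Other falls were those of POSTN (10.5-fold), FNTA (8.49-fold), MX1 (7.25-fold), ANGPTL4 (7.13-fold) and OAZ1 (7.06-fold), and RBP7 fell at least 4.03-fold. The fold of POSTN is imprecise, because its values at 188 dpn lay on both sides of the background.

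Every called gene of the interferon-response, matrix and endothelial lists went down in this interval. Interferon-response and antigen-presentation genes had 22 of 38 lower and 0 higher (29 and 0 over the list alone; adjusted p = 2.5e-10, and adjusted p = 0.157 with an estimated correlation), including ISG15 (6.08-fold), RSAD2 (408 to 64.4) and XAF1 (at least 3.09-fold). Matrix genes had 21 of 31 lower and 0 higher (26 and 0 over the list alone; adjusted p = 8.1e-12, and adjusted p = 0.141 with an estimated correlation), with ASPN at log2 -2.81, COL1A2 at -1.90 and the crosslinking enzyme LOX from 221 to 62.6. Endothelial genes had 11 of 21 lower and 0 higher (13 and 0 over the list alone; adjusted p = 3.1e-06, and adjusted p = 0.117 with an estimated correlation), including PECAM1 (3.71-fold), CDH5 (3.51-fold) and CLDN5 (2.98-fold). Cell cycle genes had 14 of 31 lower and 0 higher (17 and 0 over the list alone; adjusted p = 0.00047, and adjusted p = 0.355 with an estimated correlation), with TOP2A from 208 to 46.3 and CENPF from 121 to 29.3, the latter not called without replicate 4 of 188 dpn (adjusted p = 0.0614).

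The oxidative metabolism and slow-twitch lists called down in this interval each had a minority of their genes called. Oxidative phosphorylation had 14 of 58 lower and 0 higher (22 and 0 over the list alone; adjusted p = 9.4e-07, and adjusted p = 0.476 with an estimated correlation), with NDUFV1 at log2 -1.23 and NDUFS7 at -1.12. Fatty acid oxidation had 9 of 30 lower and 0 higher (12 and 0 over the list alone; adjusted p = 0.0059, and adjusted p = 0.485 with an estimated correlation), including ECI1 (3.73-fold), HADHA (3.09-fold) and ACADVL (2.93-fold). The added slow-twitch list had 5 of 12 lower and 0 higher (9 and 0 over the list alone; adjusted p = 5.1e-05, and adjusted p = 0.231 with an estimated correlation), with the cardiac calsequestrin CASQ2 4.71-fold, the fatty acid binding protein FABP3 3.84-fold, TPM3 2.59-fold and MYL3 2.55-fold lower. Without replicate 2 of 188 dpn MYL3 was not called (log2 -0.93, adjusted p = 0.148). The added cycle list had 8 of 21 lower and 0 higher (10 and 0 over the list alone; adjusted p = 9.5e-05, and adjusted p = 0.231 with an estimated correlation), with MDH1 at log2 -1.15 and IDH3B at -1.07. IGF2 fell a further 4.61-fold (3116 to 675, log2 -2.20, SE 0.40).

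The stress, clock, Z-disc and proteasome lists were called up from 28 dpn to 188 dpn, each with a minority of its genes called. Immediate-early and heat-shock genes had 7 of 27 higher and 1 lower (9 and 1 over the list alone; adjusted p = 0.0019, and adjusted p = 0.192 with an estimated correlation), with FOS 6.70-fold, JUN 3.51-fold and the chaperone HSPH1 2.99-fold higher. Clock genes had 3 of 10 higher and 0 lower (4 and 1 over the list alone; adjusted p = 0.0115, and adjusted p = 0.169 with an estimated correlation), with the repressor CRY2 at log2 1.42, NAMPT at 1.25 and USP2 at 0.86. The calls of NAMPT and USP2 were each lost with single samples left out, with highest adjusted p values of 0.123 and 0.0825. The added Z-disc list had 4 of 20 higher and 0 lower (5 and 0 over the list alone; adjusted p = 0.0111, and adjusted p = 0.291 with an estimated correlation), including XIRP1 (3.96-fold) and PDLIM3 (3.03-fold). The added proteasome list had 6 of 34 higher and 2 lower (7 and 2 over the list alone; adjusted p = 1.95e-05, and adjusted p = 0.273 with an estimated correlation), with PSMD11 at log2 1.02. The skeletal muscle list was not called in this interval (1 of 27 higher, 1 lower, adjusted p = 0.932).

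Over the whole span from 94 dpc to 188 dpn, imprinted and matrix genes were among those with the deepest falls. POSTN fell 116-fold (11227, SD 2915, to 113, SD 127; log2 -6.86, SE 0.51, n = 6 and 4, adjusted p = 1.0e-09), and PEG10 fell 102-fold (17078 to 152, log2 -6.68, SE 0.19, adjusted p = 3.2e-16). In the 4 animals of 188 dpn POSTN was 302, 44.7, 79.8 and 27.2, on both sides of the background of 69.7, so its fold is imprecise. The cystatin CST6 rose from a mean below background (33.5 to 2366, adjusted p = 6.4e-08), and PYGM rose 47.7-fold by 1 probe set (220 to 11285, log2 5.58, SE 0.18, adjusted p = 9.0e-16). Other rises were those of PDK4 (43.2-fold), MSS51 (38.9-fold), C4BPA (33.2-fold), GPX3 (22.3-fold) and ME1 (21.1-fold), and CYP3A29 rose at least 6.66-fold. At 188 dpn GPX3 was 12559 in replicate 4 and 704 to 1588 in the other 3, and without replicate 4 its change was log2 3.64 (adjusted p = 0.000273), against 4.48. Other falls were those of IGSF1 (55.1-fold), MEG3 (33.0-fold), ASPN (32.6-fold), TNNT2 (25.7-fold) and THBS2 (24.3-fold), and the growth factor PTN fell at least 10.1-fold. TNNT2 was at log2 -4.69, and at -5.57 without replicate 1 and -4.00 without replicate 4 of 188 dpn. Imprinted and fetal growth genes had 6 of 9 lower and 1 higher (adjusted p = 0.0196, and adjusted p = 0.142 with an estimated correlation), with IGF2 17.9-fold (log2 -4.16, SE 0.40) and PLAGL1 14.3-fold lower. AFP was at least 3.05-fold lower, but at 94 dpc it ranged from 6.96 to 1693, highest and lowest in the same animals as the liver gene AHSG.

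Several muscle lists were called up from 94 dpc to 188 dpn, whereas the slow-twitch (adjusted p = 0.761) and myogenic regulator (0.304) lists were not called and the embryonic list was called down. Of 27 skeletal muscle genes 21 were higher and 0 lower (22 and 0 over the list alone; adjusted p = 3.0e-10, and adjusted p = 0.141 with an estimated correlation), with MYH2 11.6-fold, ATP2A1 11.1-fold and the regulator MYF6 5.00-fold higher. All 10 genes of the added fast-twitch list were higher (adjusted p = 4.1e-07, and adjusted p = 0.151 with an estimated correlation), and the added glycolysis list had 15 of 18 higher and 1 lower (adjusted p = 6.2e-08, and adjusted p = 0.151 with an estimated correlation), with PHKB, GPD1 and PFKM at log2 3.42, 3.39 and 3.38. The added embryonic list had 6 of 7 lower and 1 higher (adjusted p = 0.0059, and adjusted p = 0.151 with an estimated correlation), with MYL4 22.5-fold and ACTC1 20.6-fold lower (ACTC1 log2 -4.37, and -5.27 without replicate 1 of 188 dpn). The added Z-disc list had 17 of 20 higher and 1 lower (adjusted p = 9.4e-08, and adjusted p = 0.147 with an estimated correlation). Calcium handling, an added list, had 4 of 7 higher and 1 lower (6 and 1 over the list alone; adjusted p = 0.0083, and adjusted p = 0.151 with an estimated correlation), with the release channel RYR1 3.64-fold higher and CASQ2 8.24-fold lower. The added cycle list had 17 of 21 higher and 1 lower (adjusted p = 4.3e-07, and adjusted p = 0.151 with an estimated correlation), with SUCLA2 at log2 2.76. The added proteasome list had 19 of 34 higher and 2 lower (20 and 2 over the list alone; adjusted p = 3.65e-06, and adjusted p = 0.254 with an estimated correlation).

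Metabolic lists that included liver enzymes were also called up over this span. Gluconeogenesis and glycogen genes had 5 of 14 higher and 1 lower (7 and 1 over the list alone; adjusted p = 0.0072, and adjusted p = 0.185 with an estimated correlation), with SLC37A4 10.7-fold, glycogenin GYG1 7.62-fold and PGM1 5.85-fold higher. Amino acid catabolism had 12 of 25 higher and 1 lower (adjusted p = 0.0044, and adjusted p = 0.185 with an estimated correlation), with BCKDHB at log2 2.62 and CDO1 at -2.38. Fatty acid oxidation had 9 of 30 higher and 0 lower (adjusted p = 0.0255, and adjusted p = 0.532 with an estimated correlation), with CRAT at log2 2.90 and ACADM at 1.87, but 0.0752 after quantile normalization. Oxidative phosphorylation had 21 of 58 higher and 3 lower (adjusted p = 4.5e-05, and adjusted p = 0.532 with an estimated correlation), but 0.937 after quantile normalization. Drug metabolism had 12 of 40 higher and 4 lower (14 and 4 over the list alone; adjusted p = 0.0438, and adjusted p = 0.355 with an estimated correlation), with ALDH2 7.39-fold higher and GSTA4 10.1-fold lower, but 0.0676 after quantile normalization. Peroxisome and antioxidant genes had 13 of 29 higher and 6 lower (14 and 6 over the list alone; adjusted p = 0.0302, and adjusted p = 0.262 with an estimated correlation), with SOD2 7.38-fold higher, but 0.216 after quantile normalization. Without replicate 4 of 188 dpn, the animal with PCK1 at 9175, ASS1 at 11165 and GPX3 at 12559, the fatty acid oxidation (adjusted p = 0.0990), drug metabolism (0.138) and peroxisome (0.0866) lists were not called. The drug metabolism list was also not called without replicate 2 of 94 dpc (0.0557) or replicate 1 or 6 of 1 dpn (0.0529 and 0.0534).

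The cell cycle, matrix and endothelial lists were called down over the same span. Cell cycle genes had 28 of 31 lower and 1 higher (adjusted p = 4.85e-08, and adjusted p = 0.169 with an estimated correlation), with UBE2C 9.55-fold and NUSAP1 7.50-fold lower, TOP2A from 533 to 46.3 and CENPF from 332 to 29.3. Matrix genes had 27 of 31 lower and 1 higher (28 and 1 over the list alone; adjusted p = 6.6e-10, and adjusted p = 0.157 with an estimated correlation). Endothelial genes had 13 of 21 lower and 1 higher (14 and 1 over the list alone; adjusted p = 0.00057, and adjusted p = 0.141 with an estimated correlation), with CDH5 at log2 -2.91 and PECAM1 at -2.28. Ribosomal protein genes had 3 of 59 higher and 8 lower, and the list was not called (adjusted p = 0.571; median log2 0.04, mean -0.05), but after quantile normalization it was called down (adjusted p = 3.0e-07). FASN was 2.59-fold lower (log2 -1.37, SE 0.31) and IGF1 1.83-fold lower (log2 -0.87, SE 0.30, adjusted p = 0.0264). The call of IGF1 was lost without replicate 2, 3 or 4 of 188 dpn (adjusted p = 0.0830, 0.0633 and 0.0949).

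Over all comparisons 36 of 144 tests of the 36 fixed lists were called (20 up, 16 down), and 21 of 40 tests of 10 added lists (16 up, 5 down). With an estimated correlation 0 remained in either family, and after quantile normalization 29 and 18 kept their call and direction. With only the even arrays at 1 dpn, 30 and 18 did, and with each array centred on its median 32 and 21 did. The following fixed lists were not called in any comparison: erythroid cells, fatty acid synthesis, cholesterol synthesis, bile acids, urea cycle, methionine and one-carbon metabolism, apolipoproteins, coagulation, complement, acute-phase proteins, the growth hormone and insulin-like growth factor axis, iron and haem, neutrophils, T and natural killer cells, B and plasma cells, cholangiocytes, adipocytes and pancreatic acinar cells. Of the added lists, myogenic regulators and Schwann cells were never called, and the neuromuscular junction list, with 2 measured genes, was not tested.

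Some transcripts departed at 1 dpn from their levels on both sides. There 867 probe sets (3.61%) were higher than at both 94 dpc and 28 dpn, and 1707 (7.11%) were lower than at both. Fits on only the stages compared gave 558 and 1048. With only the even arrays the counts were 600 and 1539, and with only the arrays of low 5' signal, described below, 1305 and 2283. The balance also depended on the scaling, with 1190 highest and 1146 lowest after quantile normalization and 1682 and 909 with centring. If the 2 lists of changes were independent, 220 and 726 would be called by both. With the animals of 1 dpn halved so that each step used different arrays, the counts were 448 to 671 and 1052 to 1354 over 20 halvings. MYO5B was among the genes that rose and fell back (130, 1537 and 204 at the 3 stages), and IGF1 and TIE1 were among those that fell and returned.

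Liver marker genes were uneven between samples, and several were dim. Albumin ALB had a mean signal of 291 (SD 316) at 94 dpc and 904 (SD 847) at 188 dpn and was not called between them (log2 1.80, SE 1.15, adjusted p = 0.246). AFP at 1 dpn (log2 -1.87, SE 0.77, adjusted p = 0.0679) and PCK1 at 188 dpn (log2 2.04, SE 0.84, adjusted p = 0.0634), each against 94 dpc, were not called either. HAMP, CYP2E1 and CYP7A1 were called in no comparison, and their largest changes were log2 -0.37, 0.73 and 0.45. CPS1 was 1.99-fold higher at 1 dpn than at 94 dpc (72.1 to 164, adjusted p = 0.0324), but not on the even arrays (adjusted p = 0.416), and it fell to 52.8 at 28 dpn. Its call at 1 dpn was lost without replicate 2 or 5 of 94 dpc (adjusted p = 0.0929 and 0.0512). It was also lost without replicate 3 or 4 of 1 dpn (0.0807 and 0.0849). Levels also differed widely within a stage. At 94 dpc AHSG was 21645 in replicate 1, 172 in replicate 2 and 1665 to 9562 in the other animals, against 29.5 to 2610 at the later stages. AFP was 1693 in replicate 1 of 94 dpc, 6.96 in replicate 2 and 99.6 to 805 in the other animals of that stage. Of 11 pancreas genes, 6 were the highest of the stage in replicate 3 of 1 dpn, where CPA1 reached 7632 against at most 880 elsewhere, PLA2G1B 3878 against 669 and CLPS 3060 against 372.

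At 1 dpn, 4 of the 6 arrays had little 5' signal. The 5'/3' signal ratio of GAPDH was 0.140 to 0.332 in replicates 2 to 5 of 1 dpn and 0.731 to 1.26 in the other 18 arrays. With replicates 2 to 5 left out, 6101 probe sets were called from 94 dpc to 1 dpn (1870 higher, 4231 lower) and 3972 from 1 dpn to 28 dpn (2679 higher, 1293 lower). Of the 7836 probe sets called with all arrays 4641 were called the same way without these 4 (59.2%), and for the step to 28 dpn 2560 of 5357 were (47.8%). The sign was kept for 97.8% and 97.4% of the called probe sets, in fits that share the other 2 arrays. With 2 arrays in place of 6, fewer changes can be called. The fits with only the 4 and only the other 2 arrays of 1 dpn called 181 and 115 probe sets in opposite directions in these 2 steps. Between the 4 arrays and the other 2 of the same stage, limma called 17 probe sets, 1 higher and 16 lower in the 4.

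**Figure D4:**
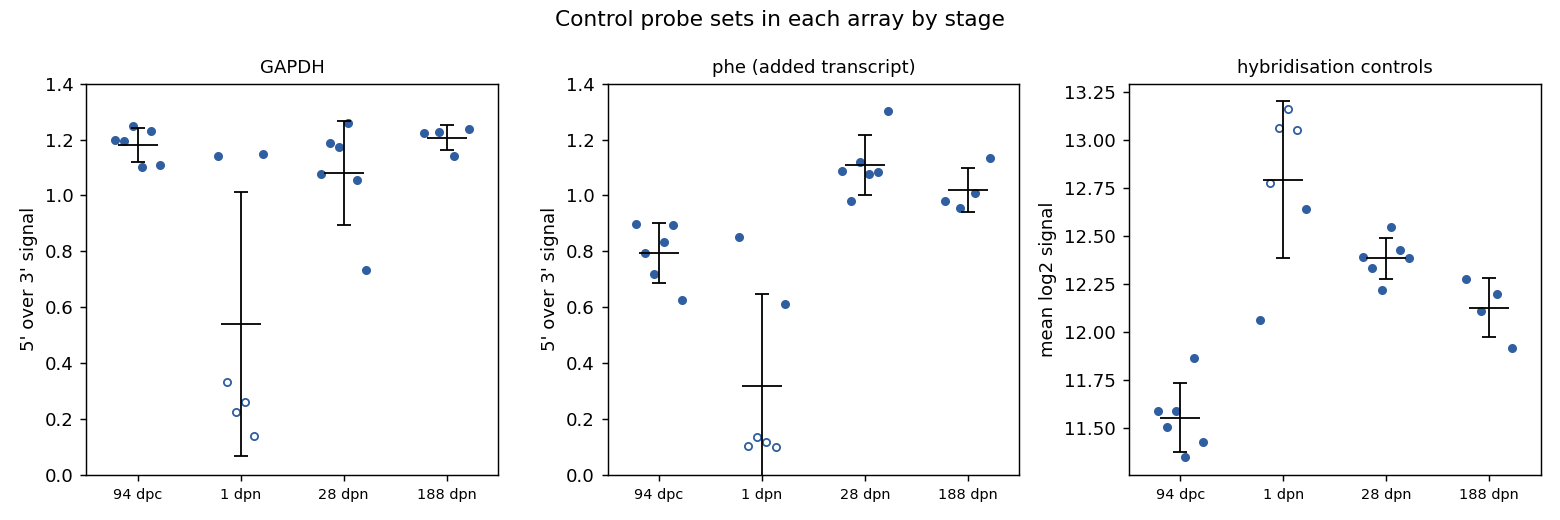
The 5'/3' signal ratio of GAPDH and of the added phe transcript, and the mean log2 signal of the hybridisation controls, per array by stage, with bars for mean and SD. The GAPDH ratio was 0.140 to 0.332 in 4 arrays of 1 dpn and 0.731 to 1.26 elsewhere.

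Arrays of the same stage were least alike at 1 dpn, in part between the 4 arrays with low 5' signal and the other 2. Correlations between arrays within a stage were 0.961 to 0.968 at 94 dpc, 0.882 to 0.931 at 1 dpn, 0.929 to 0.942 at 28 dpn and 0.930 to 0.940 at 188 dpn, against 0.835 to 0.929 between stages. Within 1 dpn they were 0.923 to 0.931 among replicates 2 to 5, 0.917 between replicates 1 and 6, and 0.882 to 0.913 across these sets. The median SD over probe sets was log2 0.30 at 94 dpc, 0.59 at 1 dpn, 0.42 at 28 dpn and 0.40 at 188 dpn, and 0.45 and 0.38 within the low and even sets of 1 dpn. A median SD tends to be lower with fewer arrays, so sets of 6, 4 and 2 arrays cannot be compared directly. The first 2 principal components held 26.5% and 16.2% of the variance.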

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

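An outlier test over 640 groups of named values singled out 40 single values, and chance alone would single out about 1 in 20 groups. The splits of animals and the same-sign tests were set before their results were seen. The tests of tissue, of the 5' ratios of added transcripts and of carried-over liver and pancreas were chosen after the pattern was seen.

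In replicate 1 of 1 dpn 10 values stood apart from the stage median: SLC31A2 97.7 (8.31), ASPN 67.1 (1096), PFKM 4905 (16326), GPD1 154 (2655), COX7A2 15990 (29877), CAPN3 8351 (417), TMEM140 634 (12.1), RBP7 10.0 (260), ANGPTL4 174 (1949) and IGSF1 169 (856). Elsewhere at 1 dpn these were CKS2 513 (218) and HADHA 6743 (12357) in replicate 6, IGF2 2403 (4295) and TYMS 60.9 (13.9) in replicate 5, and XAF1 25.4 (91.9) in replicate 4. In replicate 3 of 28 dpn 5 stood apart: MDK 195 (629), C3H2orf40 2277 (335), GAMT 2434 (4979), FOS 2167 (549) and THBS2 4468 (1168). Others at 28 dpn were COL1A2 832 (1846) in replicate 6, MYH2 40149.5 (79701) in replicate 4, CA3 45178 (28167) in replicate 1 and AFP 6.33 (61.3) in replicate 2.

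At 188 dpn replicate 2 had ANGPT2 at 187 (147), PYGM at 66346 (54659), IDH3A at 2203 (1465) and PGAM2 at 78789 (65030). Replicate 4 had ATP5I at 151 (1809), replicate 3 a GAPDH 5'/3' ratio of 1.14 (1.22), and replicate 1 a median log2 of the liver genes of 7.09 (6.62). At 94 dpc the values were CDKN3 589 (784) and TYMS 67.7 (147) in replicate 1, MYBPC1 28901 (24021) in replicate 2, CYP7A1 34.6 (2.85) in replicate 3, and MYF6 789 (1239) in replicate 4. Replicate 5 had PHKB at 1041 (1441) and CYP3A29 at 42.3 (3.87), and replicate 6 had FNTA at 17966 (23391) and SOD2 at 811 (1181).

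The tissue of the samples was weighed first. ALB lay below background on 4 arrays, and on every array the median over the 51 liver genes lay within log2 1.35 of those 4, each probe set against itself, which excludes liver as the main tissue. With 11 muscle genes and 0 liver genes among the 30 brightest, the arrays may have measured skeletal muscle, as the series title says. That count sets single probe sets against one another. Over the whole lists, the median of the 27 muscle genes lay log2 6.76 to 9.80 above that of the 51 liver genes on all 22 arrays. These values argue against a tissue without muscle, while which muscle was taken, or what mixture, stays open. A mixture of tissues was not modelled.

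The low 5' signal of 4 arrays at 1 dpn was weighed second. The highest phe ratio in these arrays was 0.134 against a lowest of 0.611 in the other 18. In the standard protocol phe is added to RNA before labelling. If that protocol was followed here, these ratios argue against loss of 5' ends in the animals' RNA alone. The highest lys ratio was 0.140 against 0.355, as a short product from the labelling of these 4 samples would give. The other added transcripts separated them barely or not at all: dap was at most 0.0659 against 0.0688, and thr was 0.0435 to 0.147 against 0.0599 to 0.484. At 94 dpc thr was 0.0599 to 0.0861 on arrays with even GAPDH signal, so these ratios also differ for other reasons, and the labelling stays an open explanation. Changes called with these arrays had the same sign in independent arrays for 86.0% of 5021 probe sets from 94 dpc to 1 dpn. From 1 dpn to 28 dpn this was 79.4% of 2051. Most of these signs therefore did not come from the 4 arrays alone. Scaling could also favour the same sign, because all arrays of 1 dpn had lower median signals (114 to 135) than those of 94 dpc (141 to 161) and 28 dpn (139 to 146). A batch shared by these 4 samples could still add to the changes. Within the stage 17 probe sets differed, but few can be called with 4 arrays against 2. On the third principal component replicates 1 and 6 lay at 88.4 and 43.5, and these 4 at -24.1 to -3.28. In the 2 steps, 181 and 115 probe sets were called in opposite directions with only these 4 arrays and with only the other 2.

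Liver and pancreas transcripts in single samples were weighed last. Deviations of the liver genes from their stage means correlated at a mean of 0.219, above the highest of 1000 random sets (0.0697), as liver RNA carried into single samples would give. The random sets were matched on mean signal only, and no other list of related genes was compared. The test therefore cannot tell carried-over liver RNA from other shared variation of these genes. In replicate 3 of 1 dpn 6 of 11 pancreas genes were the highest of the stage, which suggests pancreas RNA in that sample. The other 5 were not: AMY2 was 9280 there and 17553 in another sample, RNASE1 224 and 510, CELA2A 62.4 and 350, GP2 19.7 and 103, and CELA1 40.7 and 89.9. Whether this arose in dissection or later was not tested.

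Regrouping the animals did not produce as many calls as the real stages did. The real grouping called 12333 probe sets by the F test, and the highest other of 100 regroupings called 1079. Fitted on only the 2 stages compared, the real split and the highest other called 7163 and 312 from 94 dpc to 1 dpn, 3347 and 13 from 1 dpn to 28 dpn, 2814 and 12 from 28 dpn to 188 dpn, and 10483 and 2 from 94 dpc to 188 dpn. For probe sets highest or lowest at 1 dpn these were 2454 and 4. In each case only the real grouping, 1 of 100, reached its own count. Regrouping cannot tell age from array processing that differed between stages, and some controls did differ. The thr ratio was 0.0599 to 0.0861 at 94 dpc and 0.423 to 0.484 at 28 dpn. Hybridisation controls were at log2 11.35 to 11.86 and 12.22 to 12.55 at these stages, while the lys ratios overlapped (0.434 to 0.571 and 0.355 to 0.664).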

How the results depend on the processing

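No paired analysis was possible because the labels give no replicate numbers that tie animals together. Centring each array on its median changed the split of calls: from 94 dpc to 1 dpn 4618 were higher and 3385 lower, from 1 dpn to 28 dpn 2201 and 3342, from 28 dpn to 188 dpn 1723 and 1145, and from 94 dpc to 188 dpn 5116 were higher. Centring also gave 1682 probe sets highest and 909 lowest at 1 dpn. These moves follow from the construction, since centring removes the difference in array medians. Fits on only the stages compared called 3347 from 1 dpn to 28 dpn (2140 higher, 1207 lower) and 1606 highest or lowest at 1 dpn (558 and 1048). With only the even 5' arrays at 1 dpn 1293 were lower at 28 dpn. With only the low 5' arrays 1325 were higher at 188 dpn than at 28 dpn, and 1305 were highest at 1 dpn. No array of 1 dpn enters the difference from 28 dpn to 188 dpn, so that move came from the variance pooled over all stages. With only the even arrays at 1 dpn 1312 were likewise higher at 188 dpn. The cause of the other moves was not tested.

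The spread at 94 dpc was 0.288 after quantile normalization, and in probe sets brighter than the median one the spreads were 0.213, 0.465, 0.284 and 0.269 in order of age. Within 1 dpn it was 0.452 in the arrays with low 5' signal and 0.379 in the even pair, values not directly comparable because the sets differ in size. With an estimated correlation 0 list tests were called. As signed -log10 adjusted p, the ribosomal list from 94 dpc to 1 dpn became -2.80 and the muscle list -0.14 after quantile normalization, and oxidative phosphorylation from 1 dpn to 28 dpn became 0.000487 on the even arrays. Of the IGF2 probe sets, 2 rose from 94 dpc to 1 dpn by log2 0.72 and 1.15. Signal over background limits the dim genes.

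Leaving out any single sample kept 51 of 57 list calls and 191 of 201 gene calls. Probe sets higher at 188 dpn than at 28 dpn ranged from 552 (without replicate 2 of 188 dpn) to 1101 (without replicate 1 of 1 dpn). Spreads ranged from 0.292 to 0.299, 0.533 to 0.584, 0.394 to 0.417 and 0.349 to 0.362 in order of age. Having fewer arrays by itself tends to lower these spreads. The lists lost were cell cycle, amino acid catabolism and proteasome from 1 dpn to 28 dpn, and fatty acid oxidation (adjusted p = 0.0990), drug metabolism (0.138) and peroxisome (0.0866) without replicate 4 of 188 dpn.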

Other observations

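HBB fell 2.99-fold from 94 dpc to 1 dpn (529 to 166, log2 -1.58, SE 0.18) and rose 1.72-fold by 28 dpn (log2 0.78, SE 0.18), while the erythroid list of 12 measured genes was not called. Other probe sets of 4 more genes disagreed in sign with the named one: SLA-DRB1 from 94 dpc to 1 dpn (log2 -1.68 and 1.22), ALAS1 (-0.74 and 1.19) and MYF6 (0.99 and -0.83) from 1 dpn to 28 dpn, and MBP from 94 dpc to 188 dpn (-1.75 and 2.56).

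Replicate 4 of 188 dpn held the highest values of several metabolic genes. In that animal PCK1 was 9175, ASS1 11165, GPX3 12559 and CYP2C33 12269. CYP2C33 was called higher at 188 dpn than at 94 dpc (65.3 to 3501, adjusted p = 0.0107), but without that animal its change was log2 1.91 (adjusted p = 0.0785), against 3.27 with all animals, and without replicate 2 or 3 it was 4.25 or 4.03. SERPINA1 was 13814 in replicate 1 of 94 dpc, 173 in replicate 2 and 618 to 4524 in the other animals of that stage. In replicate 3 of 1 dpn, PRSS2 was 1185, CPB1 338 and PNLIPRP2 318.

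Hybridisation controls rose in mean log2 signal from 11.55 at 94 dpc to 12.79 at 1 dpn (13.01 in the 4 arrays with low 5' signal), and were 12.38 and 12.12 at the later stages. The median signal per array averaged 150, 123, 143 and 122 in order of age. With the GAPDH ratio as a covariate the comparisons called 6011, 4225, 3479 and 9306 probe sets, and without the 2 arrays with most liver or pancreas transcripts 6666, 4617, 2642 and 8275.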
